A study of Homo sapiens with 2 samples.

How the data were processed

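Total RNA of 2 FaDu cultures, 1 infected with pCDH-ARID3B lentivirus and 1 with the vector control, was hybridised to single-colour Agilent arrays. Per the labels' protocols, FaDu cells grew in RPMI with 10% fetal bovine serum. Virus was packaged in 293T cells, harvested 48 and 72 h after transfection and applied as a 10-fold concentrate with 8 ug/ml polybrene. The labels call the control the pCDH vector, and the series' design text calls it pCDH-GFP. From 0.2 ug of total RNA, Cy3-labelled cRNA was made by in vitro transcription, and 0.6 ug of it was fragmented for 30 min at 60 °C.

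The authors deposited each array's scanner output, whose values are spot intensities on a linear scale. Per the file headers, these intensities came from Agilent Feature Extraction 10.5.1.1 with protocol GE1_105_Dec08, and the processed signal was background-subtracted and detrended within each array, with no scaling between arrays. Probe coordinates are those of the files (hg19). Whether a probe lies in a coding exon or a UTR was not examined here. The authors also deposited a value table, whose log2 values were compared with the scanner output. Its columns had the same median (7.17) and the same sorted values within 0.02, which in turn lay within 0.01 of the mean of both arrays' sorted log2 signals. The columns correlated with their own array at 0.9998 over probes, and that of the vector control with the other array at 0.971. The table thus holds quantile-normalized log2 signals with no centring of genes, and its direction per array is known. It was used as an alternative.

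The main values were log2 processed signals minus each array's 75th percentile over non-control probes. Control spots and spots carrying an outlier flag were left out (2678 and 2884 non-control spots on the vector control array and the array labelled ARID3B). This removed 2973 of 50599 probes. Spots of a probe were averaged: 902 probes were printed 10 times and 49697 once. A probe was measured on an array if it was well above background in at least 50% of its spots there. A gene took the values of its probe with the highest mean over both arrays. For genes measured on 1 array only, the difference is a lower bound: the bright value minus the higher of the dim value and the lowest normalized signal among probes well above background on the dim array (-4.73 on the vector control array, -4.22 on the other). Gene names came from the files' accessions through a RefSeq gene table of the GRCh38.p14 assembly, used for names only: 29033 probes were named by accession, 2958 by symbol and 571 by an older symbol, and 18037 kept the file's name, which gave 34572 genes. Of these, 2071 were measured on the vector control array only and 610 on the array labelled ARID3B only.

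Samples were grouped by their labels. With 1 array per group there is no test, so genes were counted by a fixed rule of size, a log2 ratio of at least 1 in either direction. For each of 36 gene lists, the median log2 ratio of the members measured on both arrays was placed among 10000 random lists of the same size drawn with replacement from 20 bins of mean signal. A list with at least 5 measured members stood apart if its median lay in the lowest or highest 2.5%. This describes these arrays and does not test the conditions. The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the ARID family, the 12 highest and 12 lowest log2 ratios among genes with a regular symbol and a mean at or above the median of measured genes, the 5 largest bounds in each direction, up to 4 members in the direction of a list that stands apart and 2 against it, up to 4 members of the stem cell, let-7, H3K9, mesenchymal, epithelial junction, p53 and apoptosis lists, and up to 2 of other lists. A regular symbol leaves out uncharacterised, long intergenic and antisense genes, such as names with LOC, LINC or orf. As exceptions, genes whose probes differ by over 1 in log2 ratio and members of near-identical families are named as such. A few genes that the rule takes are not reported here.

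Signal over background sets the precision of single values. Repeated spots without outlier spots gave an SD of log2 ratios of 0.06 for probes at or above the median signal and 0.20 below it. With outlier spots kept, the SDs were 0.09 and 0.35. The gene table and the size rule were tested on simulated arrays of the vector control and ARID3B groups with spot noise like that measured: over 24388 genes, 50 of 50 genes with a log2 ratio of 1.5 and 49 of 50 with -1.5 were recovered, as were 50 of 50 each at 3 and -3, and 8 unchanged genes passed 2-fold. The noise put in was that of the vector control array's repeated spots without outlier spots, and all probes of a gene were shifted alike. The simulation thus leaves out disagreement between probes and the spread between cultures, and gives no error rate for the real arrays. Of 100 simulated lists of 30 members with no shift 6 stood apart, and of 100 shifted by 0.3, 91 did. Both arrays lay on 1 slide, so the slide could not be used as a block. The alternatives were median scaling, the 75th percentile over probes well above background on both arrays, quantile normalization, cyclic loess, no scaling, normexp background correction with an offset of 50, the authors' value table, stricter and no filters on dim probes, the mean of all probes, outlier spots kept, other size thresholds and unmatched random lists. Scaling to the spike-ins was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for normexp, quantile normalization and cyclic loess, were used.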

Results

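Gene expression was measured on 2 single-colour oligonucleotide arrays hybridised with total RNA from FaDu cells, an established line from a squamous cell carcinoma of the human hypopharynx. One culture had been infected with a lentivirus carrying ARID3B, a DNA-binding protein of the AT-rich interaction domain family, and the other with the vector control. Each group held 1 array, so no difference below has a replicate check, no test between the groups was possible, and no p-value is given. Both arrays lay on the same slide. Of 58717 non-control spots, 44937 (76.5%) were well above background on the vector control array and 42584 (72.5%) on the array labelled ARID3B, and no spot was saturated on either. The number of arrays limits the precision. Values are normalized log2 signals, in which 0 is the 75th percentile of the array, and a log2 ratio is the array labelled ARID3B minus the vector control.

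The signal of ARID3B itself was lower on the array labelled ARID3B. Its only probe, on chromosome 15 from 74890377 to 74890436 (hg19), read 2.27 on the vector control array and 1.31 on the array labelled ARID3B. The log2 ratio was -0.95, a signal 1.94-fold lower, and 3.14% of the genes measured on both arrays had a lower ratio. The file places this 60-base probe (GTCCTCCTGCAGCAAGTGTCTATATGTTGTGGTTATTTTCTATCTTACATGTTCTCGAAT) at position 4145 of its target transcript, and the labels do not state which part of ARID3B the vector carried. If the vector lacked this part, the probe read the cells' own transcript and checked no label. Every direction below therefore rests on the label of the array, and exchanged labels would turn all of them around. Among relatives of ARID3B, ARID3A differed little (log2 ratio 0.10), ARID5B was 1.85-fold lower (-0.89) and ARID5A 1.56-fold lower (-0.64). ARID3C, a dim gene, was 3.46-fold lower (-1.79). The other family members lay between -0.16 (KDM5C) and 0.31 (ARID1A and KDM5B), with ARID1B at 0.08, ARID2 at 0.09, JARID2 at 0.03 and ARID4A and ARID4B at 0.30 each. The small positive ratios of ARID3A, ARID1B, ARID2 and JARID2 turned negative when arrays were scaled to their medians, and that of KDM5C turned positive with scaling to the spike-ins. The median of the family's 13 measured members was 0.08 (percentile 81.0 of the random lists) and -0.03 with median scaling. A further ARID1B probe gave 2.27, and its probes thus disagreed.

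Of the 24389 genes whose brightest probe was measured on both arrays, 1080 (4.43%) were at least 2-fold higher and 675 (2.77%) at least 2-fold lower on the array labelled ARID3B. Among them 205 were at least 4-fold higher and 94 at least 4-fold lower. With the genes well above background on 1 array only, the counts came to 1600 higher and 1337 lower genes, and of those added, 391 and 247 had a bound of at least 2-fold. Which direction held more genes depended on the scaling. Median scaling gave 1344 higher and 1641 lower genes. Scaling to the spike-ins, an alternative chosen after the data were seen, gave 2173 higher and 992 lower genes. The log2 ratios had an SD of 0.58 over genes. Without outlier spots, single spots of probes printed 10 times per array had log2 ratios with an SD of 0.06 for bright probes and 0.20 for dim ones. Of these spots, 1 of 6626 deviated by 2-fold or more. With outlier spots kept, the SDs were 0.09 and 0.35, and 42 of 7650 spots deviated by 2-fold or more. These figures leave out the spread between cultures. Different probes of a gene agreed less well: over 4816 genes with a second measured probe, the difference between both ratios had an SD of 0.59. The other probe had the same sign in 125 of 155 higher genes and 111 of 138 lower genes, and passed 2-fold in 60 and 49 of them.

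**Figure D1:**
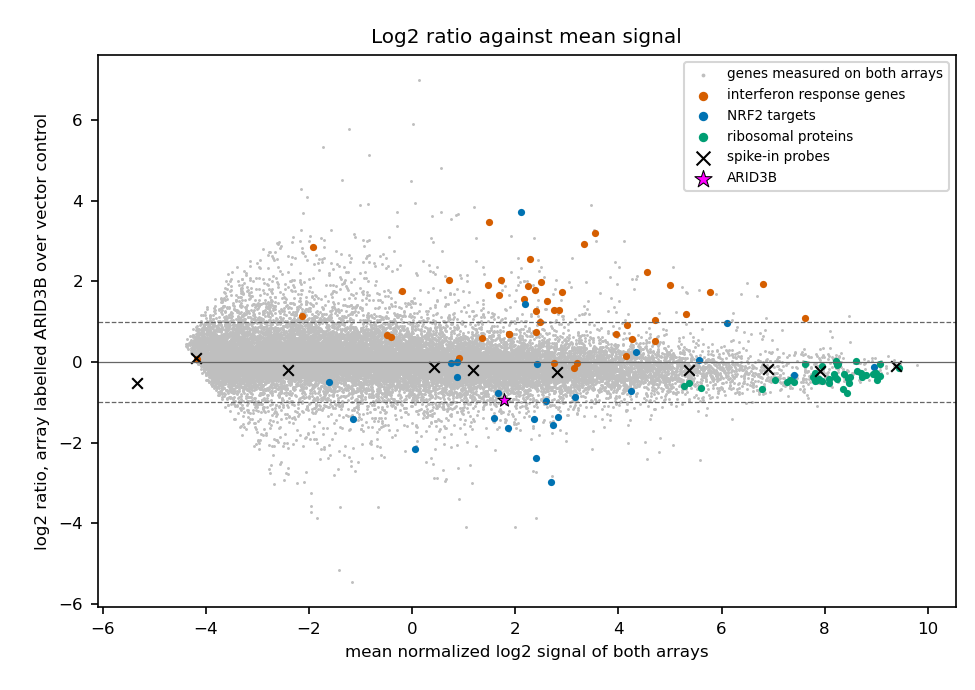
Log2 ratio (array labelled ARID3B over vector control, vertical axis) against the mean normalized log2 signal of both arrays (horizontal axis), 1 point per gene measured on both arrays. Dashed lines mark 2-fold, colours mark members of 3 gene lists, crosses the 10 spike-in probes and the star ARID3B at -0.95; interferon response genes lie mostly above the upper line.

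Among the brighter genes with a regular symbol, which leaves out the long intergenic RNAs given below, IGF2 and S100A8 had the highest ratios. IGF2, an imprinted fetal growth factor, read -2.94 on the vector control array and 2.96 on the array labelled ARID3B, 60.0-fold higher (chromosome 11, 2150394 to 2150453, hg19). Its second probe gave a log2 ratio of only 1.16, so the probes disagreed on the size of the difference. S100A8, a calcium-binding alarmin of squamous epithelium, was 14.95-fold higher (1.52 against 5.42; chromosome 1, 153362548 to 153362607). The sphingosine-1-phosphate transporter SPNS2 was 14.3-fold higher, the sushi-domain protein SUSD2 13.3-fold, the haem-degrading enzyme HMOX1 13.1-fold, the vasoconstrictor EDN2 12.5-fold and the cytokine TNF 12.3-fold. They were followed by XAF1 (11.2-fold), the matricellular proteins SMOC2 (10.4-fold) and FSTL1 (9.62-fold), the interferon-induced IFI6 (9.24-fold) and the retinoic acid carrier CRABP2 (8.74-fold). Second probes of SUSD2, XAF1 and SMOC2 gave log2 ratios of 4.23, 3.54 and 3.54, whereas that of CRABP2 gave 0.19.

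By the same rule, IL7R and MMP1 had the lowest ratios. IL7R, the interleukin-7 receptor, was 17.0-fold lower on the array labelled ARID3B (4.04 against -0.05; chromosome 5, 35876781 to 35876840). The collagenases MMP1 (chromosome 11, 102660697 to 102660756) and MMP13 (chromosome 11, 102813773 to 102813832) were 16.9-fold and 12.1-fold lower. The lymphangiogenic factor VEGFC was 14.5-fold lower (4.34 against 0.48). AMIGO2, an adhesion molecule, was 10.47-fold lower, the proteoglycan SPOCK1 8.05-fold, the glutathione peroxidase GPX2 7.84-fold and the homeobox gene HOXD10 7.70-fold. NIPAL4 was 7.47-fold lower, the serpin SERPINB13 7.37-fold, the ERK phosphatase DUSP6 7.12-fold and the Wnt antagonist DKK1 6.57-fold. None of these 12 genes had a second measured probe.

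**Figure D2:**
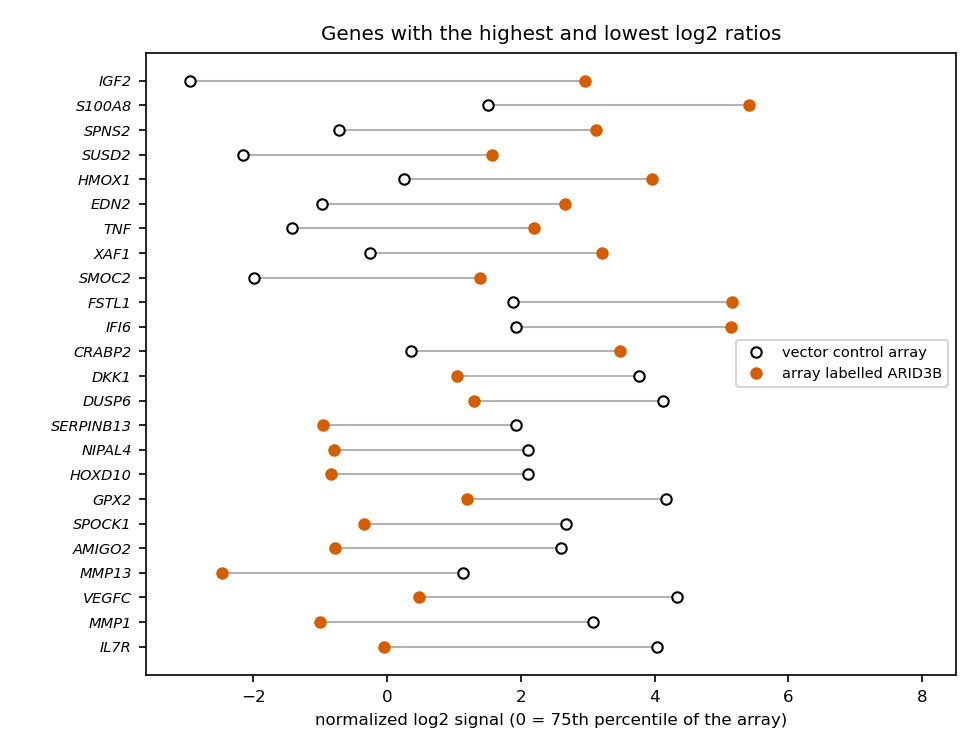
Normalized log2 signal (horizontal axis, 0 is the 75th percentile of the array) of the 12 genes with the highest and the 12 with the lowest log2 ratio among genes measured on both arrays that have a regular symbol and a mean signal at or above the median of measured genes, with an open circle for the vector control array and a filled circle for the array labelled ARID3B. S100A8 lies at 1.52 and 5.42, and IL7R at 4.04 and -0.05.

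Some genes were well above background on 1 array only, so that their difference is a lower bound. On the array labelled ARID3B alone, the GTPase RRAD was at least 31.1-fold higher, the homeobox gene NKX3-2 at least 14.7-fold, the class II antigen-presenting chain HLA-DRA at least 12.9-fold, the long RNA CEROX1 at least 12.01-fold and SNORD116-27, one of many near-identical copies, at least 11.4-fold. On the vector control array alone, the calcium channel CACNA1D was at least 28.2-fold higher than on the other, CLEC12A at least 19.6-fold, the Wnt modulator SFRP4 at least 16.2-fold, PROX2 at least 12.3-fold and OBP2A at least 10.6-fold. PROX2 had a second probe, with a log2 ratio of -2.61. The values of the other 9 rest on 1 measured probe each.

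Across the 36 gene lists fixed before the data were examined, 14 had a median in the outer 5% of random lists matched on mean signal, 7 above and 7 below. For lists of independently drawn genes 1.8 would be expected. The lists here share some members, such as SLC7A11, and members of a list may vary together. The count of 14 therefore does not measure an excess over chance. Interferon response genes stood out most. Of 44 measured members, 28 were at least 2-fold higher, none was 2-fold lower and 41 had a positive ratio. Their median log2 ratio was 1.27 (2.42-fold), above all 10000 random lists, whose central 95% ran from -0.25 to 0.01. Beyond XAF1 and IFI6, the largest were IFI44L (7.59-fold) and the chemokine CXCL10 (7.22-fold), whose second probe gave a log2 ratio of 2.92. The RNA helicase DDX60 (-0.14) and the DNA sensor IFI16 (-0.03) were lowest, and both turned positive with scaling to the spike-ins and with cyclic loess.

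Inflammatory genes driven by NF-kB went both ways. Of 34 measured members, 10 were at least 2-fold higher and 7 at least 2-fold lower, and the median was 0.25, above all random lists. After TNF, the complement component C3 was 7.96-fold higher (2.07 against 5.07), the lymphotoxin LTB 5.61-fold and the siderophore binder LCN2 4.38-fold. PTGS2, the inducible cyclooxygenase, was 4.03-fold lower and the growth factor CSF2 3.01-fold lower.

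Genes of squamous differentiation and mesenchymal genes also had higher medians. Of 42 squamous differentiation genes, 9 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.16 (percentile 98.9). The suprabasal protein SBSN was 34.9-fold higher, S100A9, the partner of S100A8, 8.46-fold and S100A7 7.88-fold. SERPINB3 was 5.58-fold lower and SERPINB4 5.13-fold lower, and these near-identical genes cannot be separated with certainty. Without a filter on dim probes the squamous list no longer stood apart (0.11, percentile 94.8). Of 27 mesenchymal genes, 5 were at least 2-fold higher and 1 lower, with a median of 0.38, above all random lists. The list was split, with 16 positive and 11 negative ratios. The matricellular protein CCN2 was 5.11-fold higher, the receptor kinase AXL 4.20-fold, the cadherin CDH11 2.29-fold by its brightest probe (-0.10 by the other) and vimentin, VIM, 2.22-fold. CDH11 and VIM were dim, at -2.76 and -2.46 on the vector control array. The lysyl oxidase LOXL2 was 2.05-fold lower and the caveolar protein CAV1 1.56-fold lower.

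Genes of the oxidative stress factor NRF2 had the lowest median. Of 25 measured members, 9 were at least 2-fold lower and 2 at least 2-fold higher, and the median of -0.73 lay below all 10000 random lists. Besides GPX2, the cystine transporter SLC7A11 was 5.19-fold lower, the aldo-keto reductase AKR1B10 4.46-fold and the UDP-glucose dehydrogenase UGDH 3.12-fold. HMOX1, also driven by NRF2, went the other way, as did the exporter ABCC3 (2.69-fold higher, its second probe at a log2 ratio of 0.29). Hypoxia and glycolysis genes had a median of -0.35 (percentile 0.13), with 6 of 37 at least 2-fold lower and none higher. The angiogenic factor VEGFA was 3.25-fold lower, the kinase PDK1 3.01-fold, ANGPTL4 2.78-fold and INSIG2 2.40-fold, while TXNIP (0.97) and ARRDC3 (0.54) were higher. Genes of the unfolded protein and amino acid stress responses had a median of -0.32 (percentile 0.43), and 2 of 41 were at least 2-fold lower. SLC7A11 and the pseudokinase TRIB3 (2.03-fold) were these, followed by SDF2L1 (-0.96) and STC2 (-0.87), with CEBPB (0.80) and PPP1R15A (0.64) on the other side.

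Genes of ribosome production were lower by small amounts, none by 2-fold. Ribosome biogenesis genes had a median of -0.42 (percentile 0.03), and 2 of 33 had a positive ratio. IMP4 (-0.86), NOP2 (-0.79), RRP1B (-0.66) and DDX21 (-0.65) were lowest, and NOP58 (0.16) and PES1 (0.10, negative with median scaling) highest. Ribosomal proteins had a median of -0.37 (percentile 0.40). RPL29 (-0.67), RPL37 (-0.66) and RPS3 (-0.63) were among the lower members, and RPS19 (0.04) and RPS16 (0.02), both negative with median scaling, were on the other side. Their random lists were themselves low (-0.33 to -0.11), since the brightest 6097 genes had a median of -0.16, and after cyclic loess the list no longer stood apart (-0.07, percentile 3.25).

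Targets of growth factor signalling had a median of -0.20 (percentile 1.80), with 11 of 43 at least 2-fold lower and 2 higher. MMP1, MMP13, DUSP6 and the stromelysin MMP10 (6.52-fold) were lowest, and the cytokines IL11 (4.28-fold) and LIF (3.17-fold) highest. With normexp background correction this list moved just inside the random range (-0.16, percentile 2.69). HOX genes had a median of -0.26 (percentile 0.13). HOXD10 and its neighbour HOXD11 (5.25-fold) were at least 2-fold lower, HOXA11 (-0.97) and HOXA9 (-0.95) came next, and HOXB3 (2.88-fold) was higher. The HOX list did not stand apart in quantile-normalized values (-0.12, percentile 8.29), with cyclic loess, in the authors' value table or with the mean of all probes.

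Histones, long intergenic RNAs and heat shock genes had medians close to 0 that still lay above their random lists. Replication-dependent histones had a median of 0.09 against a random range of -0.24 to -0.03, with H2AC19 (2.39-fold) and H2BC12 (2.30-fold, its other probe at 0.11) highest, H2AC7 (0.72) and H1-2 (0.69) next, and H2AC2P (-0.65) and H4C4 (-0.30) lowest. These genes share near-identical sequence, so single members are uncertain. Long intergenic RNAs had a median of 0.11 (percentile 99.2), with 24 of the 432 measured on both arrays at least 2-fold higher and 8 lower. By their brightest probe, a further 70 were above background on the vector control array only and 17 on the array labelled ARID3B only. Genes at large leaned the same way: by any probe, 2071 were measured on the vector control array only and 610 on the other only. This lean is thus not particular to long intergenic RNAs. The lowest normalized signal well above background was also higher on the array labelled ARID3B (-4.22 against -4.73). Its negative control spots spread more, with an SD of 6.27 against 4.29 on the linear scale. How far this accounts for the lean was not tested. LINC00598 (127-fold), LINC00880 (40.6-fold) and LINC00867 (15.3-fold) led by their brightest probes. The other probe of LINC00598 gave 0.14 and that of LINC00867 0.12, and the 8 other measured probes of LINC00880 all went the opposite way, from -2.25 to -0.20. LINC00960 (11.7-fold) had none. LINC00332 (3.45-fold) and LINC01124 (3.24-fold) were lower. Metallothioneins and heat shock genes had a median of 0.03 (percentile 97.9), from HSPA1A (0.44), HSPA1B (0.34), HSPA6 (0.34) and MT1M (0.20) to HSPA4L (-0.50) and BAG3 (-0.42). HSPA1A and HSPA1B are near-identical genes and cannot be separated with certainty. With median scaling all 3 medians were negative (-0.02, -0.003 and -0.08). Against unmatched random lists, histones (percentile 92.5) and heat shock genes (60.4) no longer stood apart, nor did long intergenic RNAs (80.0) and heat shock genes (96.6) without a filter on dim probes.

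**Figure D3:**
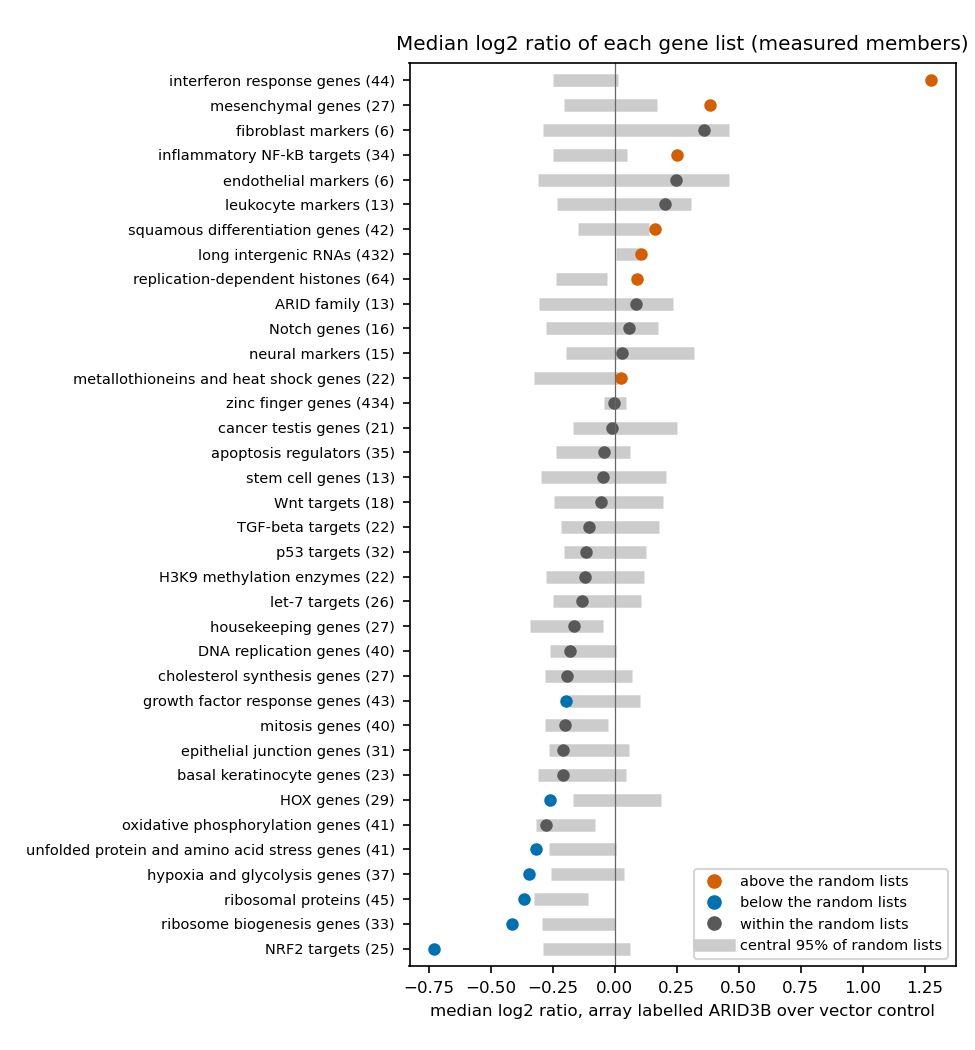
Median log2 ratio (horizontal axis, array labelled ARID3B over vector control) of the 36 gene lists, with the number of measured members in parentheses. Grey bars give the central 95% of 10000 random lists matched on mean signal; interferon response genes (1.27) and NRF2 targets (-0.73) lie farthest from theirs.

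Stem cell genes, targets of the microRNA let-7, enzymes of H3K9 methylation, epithelial junction genes, p53 targets and apoptosis regulators did not stand apart from random lists. Stem cell genes had a median of -0.05 over 13 measured members (percentile 50.1). The aldehyde dehydrogenase ALDH1A3 was 2.68-fold lower and MYC 2.24-fold lower by 1 probe (0.05 by the other), while SOX2 (0.66) and SALL4 (0.62) were higher. NANOG and CRIPTO, both dim and named after their values were seen, were measured on 1 array only, NANOG on the array labelled ARID3B (at least 3.39-fold higher there) and CRIPTO on the vector control array (at least 1.04-fold). Without a filter on dim probes the median was 0.35 (percentile 97.52), just past the limit. That median takes in NANOG, CRIPTO and 4 members above background on neither array. Targets of let-7 had a median of -0.13 (percentile 27.8), with the cyclin CCND2 (2.30-fold) and IGF2BP1 (2.04-fold) higher, MYC the only one at least 2-fold lower, and IGF2BP2 at -0.88. H3K9 methylation enzymes had a median of -0.12 (percentile 34.7), none differed by 2-fold by its brightest probe, and the largest ratios were those of the demethylases KDM7A (-0.86, with -1.22 by its other probe) and KDM4D (-0.69), the methyltransferase SETDB2 (-0.60) and the reader CBX3 (-0.56). Epithelial junction genes had a median of -0.21 (percentile 9.95). The transcription factors ELF3 (log2 ratio 1.32) and EHF (-1.32) went opposite ways, and the claudin CLDN3 (2.27-fold) and TJP3 (2.08-fold) were higher. Targets of p53 had a median of -0.12 (percentile 17.9), with TP53I3 3.45-fold higher and PMAIP1, GADD45A and POLH 3.19-fold, 2.66-fold and 2.11-fold lower. Apoptosis regulators had a median of -0.05 (percentile 75.2). BMF was 7.06-fold higher by its brightest probe (0.53 by the other), while CASP10 stood at a log2 ratio of -1.32 (0.49 by the other), BIK at -0.89 and TNFRSF10A at 0.87. TNFRSF10A was dim, at -4.62 on the vector control array. The medians of the stem cell and apoptosis lists were positive in several scalings, including cyclic loess (0.04 each), and those of the let-7, H3K9 and p53 lists with scaling to the spike-ins (0.05, 0.06 and 0.06).

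Lists of cell division and metabolism lay within their random ranges. DNA replication genes had a median of -0.18 (percentile 22.1), with CHAF1B 2.42-fold lower and MCM5 at 0.95, and mitosis genes one of -0.20 (percentile 21.4), with BUB1 at -0.82 and CCNA2 at -0.78. Oxidative phosphorylation genes (-0.28, percentile 9.42; CYC1 -0.51, ATP5PO -0.49) and cholesterol synthesis genes (-0.19, percentile 16.8; FASN 2.22-fold lower) lay at the lower side. Housekeeping genes had a median of -0.17 (percentile 62.4), which was positive with cyclic loess (0.02) and with scaling to the spike-ins (0.02), with GAPDH at -0.51 and B2M at 0.58. Basal keratinocyte genes had a median of -0.21 (percentile 18.6), with the keratin KRT6B 4.72-fold higher and dystonin, DST, 2.73-fold lower by its brightest probe. Wnt targets (-0.06, percentile 39.5) included DKK1 and APCDD1 (2.36-fold higher), Notch genes (0.06, percentile 83.7) JAG1 (3.31-fold lower) and DTX3L (2.92-fold higher), and TGF-beta targets (-0.10, percentile 21.5) MMP13 and CCN2. The signs of the Wnt, Notch and TGF-beta medians differed between scalings. Cancer testis genes (-0.01, percentile 32.8; MAGEC2 2.32-fold higher, LIPI 0.43, both dim) and zinc finger genes (-0.005, percentile 40.8; ZNF177 4.21-fold higher, ZNF114 3.09-fold lower) were centred near 0, with signs that differed between scalings.

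Markers of other cell types gave no list that stood apart. Fibroblast markers had a median of 0.36 over 6 measured genes (percentile 93.6), with COL1A1 5.47-fold higher and FAP at 0.95, and with the mean of all probes the list passed the limit (0.50, percentile 98.3). Leukocyte markers had a median of 0.20 over 13 genes (percentile 90.7), with CD52 3.10-fold higher and LCP1 3.17-fold lower. On the vector control array FAP (-4.47) and CD52 (-4.43) lay near the lowest signal well above background (-4.73). Endothelial markers (0.25 over 6 genes, percentile 84.7; EGFL7 2.04-fold lower, VWF 0.75) and neural markers (0.03 over 15 genes, percentile 41.9, negative in some scalings; ELAVL4 3.33-fold lower, INA 2.61-fold higher) lay within their ranges.

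The spike-in controls were slightly lower on the array labelled ARID3B. Over 10 spike-in probes the log2 ratio had a median of -0.19 and ran from -0.53 for the dimmest to 0.11. The 8 well above background on both arrays gave the scaling alternative, which moved the median of all genes by 0.18.

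Of the named genes past 2-fold, 22 did not pass it the same way in at least 1 alternative: ABCC3, APCDD1, ARID3C, CASP10, CD52, CDH11, CLDN3, DST, EGFL7, ELAVL4, FASN, H2BC12, IGF2BP1, INSIG2, LINC00880, LOXL2, MAGEC2, MYC, POLH, TJP3, TRIB3 and VIM. IGF2BP1 (0.92) and TJP3 (0.94) did not with median scaling, and EGFL7 (-0.95), LOXL2 (-0.96), POLH (-0.998) and TRIB3 (-0.94) did not with the 75th percentile over probes well above background on both arrays.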

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

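Scaling to the spike-ins was chosen after the data were seen; the other alternatives were not. The ARID3B ratio was negative in every alternative, from -1.06 to -0.77: -1.06 with median scaling, -0.87 with the 75th percentile over probes well above background on both arrays, -0.86 after quantile normalization, -0.85 after cyclic loess, -0.86 in the authors' value table and -0.77 with scaling to the spike-ins. Median scaling moved the median of all genes by -0.11. The counts of genes at least 2-fold higher and lower were 1344 and 1641 with median scaling, which turned their balance around, 818 and 624 with normexp and its offset, 675 lower genes among those measured on both arrays, 3459 and 3180 at 1.5-fold, 771 and 648 at 3-fold, and 351 and 376 among the brighter genes. Interferon, mesenchymal, NF-kB, hypoxia, unfolded protein, NRF2 and ribosome biogenesis genes, 7 of the 14 lists, stood apart the same way in the 8 alternatives that moved percentiles of lists; the other 5, which shift all genes alike or keep the same genes, could not move them. With median scaling the medians of histones (-0.021), long intergenic RNAs (-0.003) and heat shock genes (-0.084) turned negative through the shift of all genes. HOX genes lost their place after quantile normalization (-0.12), cyclic loess (-0.11), in the authors' value table (-0.13) and with the mean of all probes (-0.10), ribosomal proteins after cyclic loess (-0.074), growth factor genes with normexp (-0.16), and squamous (0.11), long intergenic (0.12) and heat shock genes (0.033) without a filter. Stem cell genes gained one without a filter (0.35), which took in 4 members above background on neither array. Fibroblast markers gained one with the mean of all probes (0.50). Against unmatched random lists, histones (0.089) and heat shock genes (0.026) no longer stood apart, and epithelial junction (-0.21), basal keratinocyte (-0.21), DNA replication (-0.18), mitosis (-0.20), cholesterol (-0.19) and oxidative phosphorylation genes (-0.28) did, because bright genes leaned lower. Apart from these shifts, the cause was not tested. Of the named genes past 2-fold, 83 were so in all 12 alternatives for genes, of which both filters left their values unchanged, and LINC00880 reversed with the mean of all probes (-0.30). The slide as a block could not be fitted. Signal over background limits dim genes, whose repeated spots spread more.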

Other observations

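Tests of spot noise, probe position, exchanged labels, other probes and cultures were chosen after the results were seen. Those with cyclic loess and the spike-ins were set before their own values were seen, for patterns found in these same data. Genes in this and the next paragraph were chosen after their values were seen and were not tested as groups. IFNB1 and IFNL1 also belong to the interferon list, and AREG, EREG, HBEGF, BTC, TGFA and MMP3 to the growth factor list. The others belong to no fixed list. Among HLA class II genes, HLA-DMA had a log2 ratio of 2.58 (1.65 by its second brightest probe), HLA-DMB of 2.24, HLA-DQA2 of 1.78, HLA-DRB5 of 1.76 and HLA-DQA1 of 1.31, HLA-DPB1 was 2.14-fold higher (log2 ratio 1.98 by its second), and HLA-DRA was above background on the array labelled ARID3B only. HLA-DRB1 (0.75), HLA-DRB4 (0.31), HLA-DQB2 (0.30) and HLA-DOA (0.05, 0.06 by its second) lay below 2-fold. The probes of HLA-DPB2 had opposite signs (0.59 and -0.32), and those of HLA-DPA1 (0.37 and 1.84) and HLA-DQB1 (0.10 and 1.38) disagreed. The probes of the class II activator CIITA disagreed as well, at -0.24 and 1.59. Class I genes were bright, with HLA-B at 0.73, HLA-C at 0.62 and HLA-F at 0.88. HLA genes share near-identical sequence, so single members are uncertain. The type III interferon genes IFNL1 and IFNL2 were 3.39-fold and 4.52-fold higher, and IFNB1 (0.08) was dim on both arrays.

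H19, an imprinted neighbour of IGF2, had log2 ratios of 2.36 and 2.56 by its probes, and the imprinted cell cycle inhibitor CDKN1C one of 2.53. IGF2-AS stood at 0.27 (-0.17 by its other probe), and the probes of KCNQ1OT1 disagreed (0.38 and 2.07). Imprinted genes elsewhere in the genome differed from each other, with NDN at 2.49, PEG3 at 1.17, MEST at 0.14, DLK1 at -0.05 and GRB10 at -0.33. Of ligands for receptors of the EGF family, AREG (-2.16), EREG (-2.08) and NRG1 (-2.48) were at least 2-fold lower, while HBEGF (-0.81), BTC (-0.22), TGFA (0.20) and EGF (0.69) were not. MMP12 was above background on the vector control array only (at least 6.38-fold higher there), as was MMP3 (at least 3.46-fold). COXFA4L3, a mitochondrial protein gene left out by the rule on names, was 28.1-fold higher on the array labelled ARID3B.

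The lower ARID3B signal on the array labelled ARID3B has several candidate explanations. Noise of single spots is argued against, since the ratio was 16.6 times the SD of single-spot ratios of bright probes without outlier spots. With outlier spots kept, that SD was 0.09. A probe outside the introduced sequence may account for the missing increase: the file places it at position 4145 of the transcript, and the labels do not say what the vector carried. Exchanged labels could account for the ratio of -0.95 through the introduced sequence only if the vector carried the probe's part of ARID3B. Otherwise the ratio says nothing about the labels. Both explanations stay open because no other probe of the gene was measured. A lower level of the cells' own transcript was not tested apart from these.

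The interferon response genes were higher as a set. A brightness-dependent difference between the arrays is argued against, since the list's median was 1.42 after cyclic loess, and faulty single probes are argued against, since the other probes of 14 members had a median of 1.07 and 12 of the 14 were positive. A difference between the cultures or viral transductions other than ARID3B cannot be told apart from an effect of ARID3B with 1 array per group.

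Ribosome biogenesis genes and ribosomal proteins were lower as sets. For ribosome biogenesis genes a brightness-dependent difference as the whole cause is argued against, since the median went from -0.42 to -0.26 after cyclic loess and still lay below the random lists. For ribosomal proteins it cannot be told apart from a change in the cells, since the list no longer stood apart after cyclic loess (-0.07). The 4 spike-ins inside their brightness range had a median of -0.18, between 0 and the list's -0.37. All 10 spike-ins had a median of -0.19. The value may thus be an offset at every brightness and cannot decide the question. A difference between the cultures stays open for both lists, untested.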
